A study of Homo sapiens with 22 samples.

How the data were processed

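A genome-wide pool of CRISPR guides was sequenced from OCI-AML2 cells, per the labels' protocols. Cells were selected with puromycin for 7 days, treatment is given from day 5 after puromycin selection, and 50 µg of DNA was used to amplify the guides, per the labels. The authors deposited one table of guide read counts for 22 sequencing runs, with the gene, chromosome, exon and position of each of 90709 guides. cutadapt, Bowtie2, SAMtools and MAGeCK were used, per the submitters' processing notes, which give no versions. The deposited counts are raw read counts without normalization. The genome build of the guide positions is not given in the sources used here. Symbols were matched to the reference gene table: 16691 were current, 1244 were older symbols with a unique match and 74 had none. Symbols are printed as the table gives them.

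The 9 libraries with 2 runs were summed, giving 13 libraries in 6 groups: 5 groups of 2 and 1 of 3. Depth ran from 24897083 to 41261585 reads per library. Guides with at least 10 reads in at least 2 libraries were kept, which left 88401 guides and removed 2308. They were tested in 1 fit of all 13 libraries, with 7 residual degrees of freedom, by edgeR 4.0.16 (TMM, glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3. Genes with at least 3 tested guides (17579) were tested by a separate implementation of robust rank aggregation as in MAGeCK. It ranked guides by the one-sided edgeR p in each direction with alpha 0.25. The null was 1000000 random guide sets of the same size, so 1e-06 is the smallest p it can give, and Benjamini-Hochberg adjustment ran over genes per direction. Guides, not cultures, are the repeated unit of that gene test. The threshold was an adjusted p of 0.05. The value given for a gene is the median of its guides' log2 fold changes from edgeR, and its level is the mean guide log2 CPM with a prior count of 2. List medians are taken over the differences of those levels.

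The comparisons were JQ1 with DMSO in parental cells at day 14, CPI-0610 with DMSO in parental cells at day 21 and JQ1 with DMSO in resistant cells at day 14. To these were added the difference between the resistant and parental JQ1 effects, the difference between the JQ1 and CPI-0610 effects in parental cells, and the DMSO libraries of the 2 lines. Groups, comparisons, tests, gene lists, the naming rule and all alternatives but 1 were set before the data were examined. Of 46 gene lists, 45 had tested members (884 genes), and the olfactory receptor pattern matched no symbol. Lists were tested two-sided with camera in limma 3.58.1 on the gene levels (preset correlation 0.01, adjusted over lists within a comparison), beside an estimated correlation and fry. For each list the gene test was also adjusted over the list alone.

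Genes were named by rule. For the drug comparisons these were the up to 12 genes per direction with the largest median among those that passed and lay on the same side in every library. Where fewer than 3 passed in a direction, the 3 with the lowest p were named. For the other comparisons it was up to 5 per direction, and for each list up to 4 members with the lowest p. BRD2, BRD3, SPOP, TRIM33, EZH2, EED and SUZ12 were always examined. Results for 3 genes and 2 gene lists are not reported here. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333, and with 3 against 2 not below 0.1, so single values were not tested that way.

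Alternatives were RLE scaling, total counts, no guide filter, a mean of at least 100 reads per guide, DESeq2 1.42.0, only the libraries of a comparison, a replicate block, non-robust fitting, the first or the additional run only, alpha 0.05, counts summed per gene, limma on gene levels, omission of each gene's strongest guide and omission of each library. A fit without the 4 parental day 14 libraries was added after seeing the data. Where an omission left 1 library in a group, that library was assumed to vary like the other groups. Rank aggregation and plots ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

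The tests were tested on simulated data drawn from the real libraries' means and sizes, with 200 genes changed in each of the 3 drug comparisons, 50 per fold size among 17562 genes. Each guide had 1 estimate of spread for all groups, and guides were drawn independently. The real parental JQ1 replicates differed more, with a chi-squared value per degree of freedom of 332.37 against 58.27 for CPI-0610 and 42.51 for resistant JQ1. The simulated shares and false calls for parental JQ1 therefore need not hold for its real libraries. For a log2 change of 2, 80% of genes were recovered in the parental JQ1, 78% in the CPI-0610 and 90% in the resistant comparison. For −2 the shares were 54%, 66% and 72%, for 1 they were 8% in each, and for −1 they were 2%, 4% and 6%. In each comparison 3 of 17362 unchanged genes were called. The guide test recovered 0 of 248 guides simulated at 2 in both parental comparisons and 2 in the resistant one. Most simulated changes of 1 log2 unit were thus not recovered in these libraries. No control guides were present in the table.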

Results

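The series addresses which genes, when knocked out, let acute myeloid leukaemia cells grow through BET inhibition. OCI-AML2 cells, an established human leukaemia line, carried a genome-wide pool of CRISPR knockout constructs, and guide sequences were counted in their DNA. A guide that is more abundant under drug than under DMSO marks a knockout carried by a larger share of the treated cells. JQ1 and CPI-0610 both block the bromodomains of BET proteins, readers of acetylated chromatin. The deposited counts covered 90709 guides against 18009 genes in 13 libraries. Parental cells gave 2 libraries each for DMSO at day 14, JQ1 at day 14, DMSO at day 21 and CPI-0610 at day 21. JQ1-resistant cells gave 3 libraries for DMSO and 2 for JQ1 at day 14. Each library held 24897083 to 41261585 reads. Drug doses were not given in the sources used here. The labels do not say that replicates were separate cultures, so the spread between libraries, on which the guide p-values rest, may be technical. Gene p-values rank a gene's guides against random guide sets, and camera sets a list against other genes. Neither measures how far a result would repeat between cultures.

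Knockout of essential genes was depleted in the parental libraries and much less so in the resistant ones. The median level of 229 ribosome, proteasome, spliceosome, RNA polymerase II and respiratory complex I genes was set against that of 112 keratin and crystallin genes, which these cells are not known to need. The difference was −3.06 and −3.91 log2 units in the parental DMSO libraries of day 14 and −4.02 and −3.31 in the parental JQ1 libraries. It was −2.18 and −2.10 in DMSO and −2.09 and −2.24 in CPI-0610 at day 21. In the resistant line it lay between −0.57 and −0.48 in DMSO and was −0.60 and −0.52 in JQ1. Genes for the cytosolic ribosome, which makes protein, lay at −3.57 ± 0.86 (SD, n = 2) in parental DMSO at day 14 and at −0.68 ± 0.05 (SD, n = 3) in resistant DMSO. Guide abundance was most uneven in the 4 parental day 14 libraries, with Gini indices of 0.695 to 0.796 against 0.424 to 0.512 elsewhere. A single guide against the histone gene HIST1H4J, chosen after its values were seen, took 560318 reads or 1.68% of parental JQ1 replicate 2. Gene effects measured with separate DMSO libraries correlated across 17579 genes between the replicates of CPI-0610 (r = 0.326 to 0.343) and of resistant JQ1 (r = 0.328 to 0.355). For parental JQ1 the same r was −0.187 to −0.103, so its 2 libraries did not repeat each other's gene effects. Genes are not independent replicates, and this check was chosen after the data were seen.

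**Figure D1:**
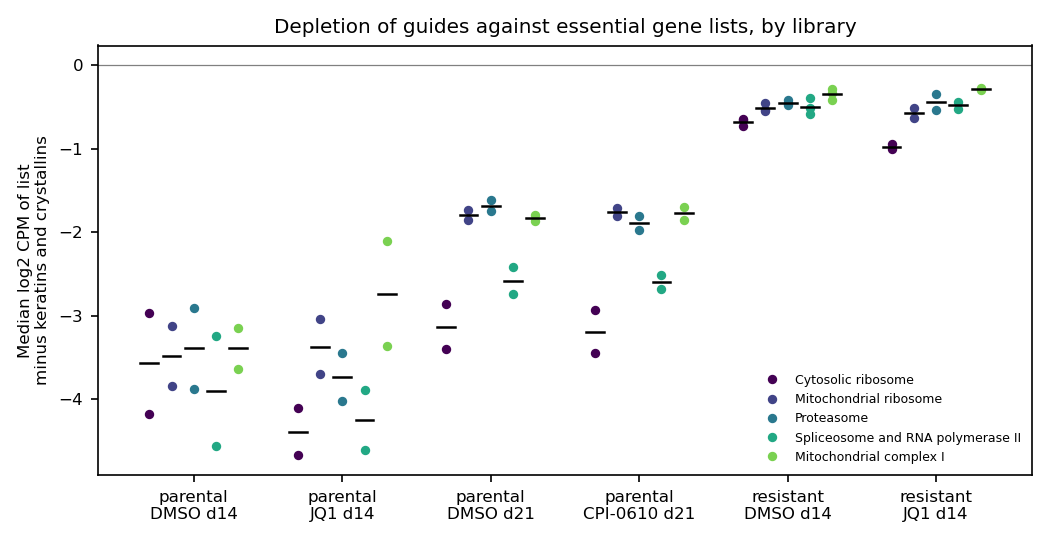
Median mean-guide log2 CPM of each of 5 essential gene lists minus that of the keratins and crystallins, per library (points) with group means (bars). In each list the resistant libraries lay nearest 0.

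The comparison of JQ1 with DMSO in parental cells at day 14 asked which knockouts were favoured or disfavoured by the drug. Guides against H2AFZ (current symbol H2AZ1), which encodes the histone variant H2A.Z, rose by a median of 2.74 log2 units (adjusted p = 0.0352). All 5 of its guides were higher, and its mean guide level was 5.97 ± 0.77 log2 CPM (SD, n = 2) under JQ1 against 3.85 ± 0.17 (SD, n = 2) under DMSO. Guides against FBXW7, the ubiquitin ligase subunit that targets MYC and cyclin E, rose by a median of 1.95 (adjusted p = 0.0176), with all 11 guides higher in the fit. The FBXW7 level was 3.84 ± 2.44 (SD, n = 2) against 2.28 ± 0.16 (SD, n = 2), because replicate 2 lay 3.28 above the DMSO mean and replicate 1 lay at −0.17 from it. The H2AFZ guides lay in exons 1 and 2 on chromosome 4 between 100870022 and 100870540, with a genome build that is not given in the sources used here. Of the genes nearest to the threshold, OAZ2, which restrains polyamine synthesis, had a median of 2.27 (adjusted p = 0.182). Guides against the proton pump subunit ATP6V0C (−3.63, adjusted p = 0.105), the ribosomal protein RPL19 (−3.77, adjusted p = 0.105) and the coat protein COPA (−3.93, adjusted p = 0.135) were lower without passing the test. The ATP6V0C guides held few reads, 0 to 2 each under JQ1 and 0 to 37 under DMSO. Robust rank aggregation on edgeR p-values called 2 genes higher and 0 lower, against 949 and 1040 genes at an unadjusted p under 0.05. limma on gene means called 1 higher and 7 lower, with neither H2AFZ nor FBXW7 among them. Both calls also ended with the replicate block and with alpha 0.05, and that of FBXW7 with counts summed per gene. At the level of single guides edgeR called 0 of 88401 (12199 at an unadjusted p under 0.05), and DESeq2 called 5009 higher and 1387 lower. Without parental JQ1 replicate 2 the FBXW7 median fell to 0.65 (adjusted p = 1), and without replicate 1 it was 2.57 (adjusted p = 0.00879). H2AFZ had an adjusted p of 0.334 without DMSO replicate 1, 0.54 without DMSO replicate 2, 0.433 without JQ1 replicate 1 and 0.0352 without JQ1 replicate 2. The gene count was 0 without DMSO replicate 1 and 20, all lower, without DMSO replicate 2, and the count of single guides was 15981 without JQ1 replicate 1 and 24197 without JQ1 replicate 2.

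Among the gene lists, the cytosolic ribosome list fell in parental cells under JQ1. Its median was −1.09 with 48 of 52 members lower, against −0.21 for all genes (adjusted p = 2.52e-07 by camera; adjusted p = 0.889 with an estimated correlation). With only the 4 libraries of this comparison in the fit its adjusted p was 0.479, and relative to the keratins and crystallins the groups overlapped, at −2.96 and −4.17 in DMSO and −4.67 and −4.10 in JQ1. RPL19, RPL13 (−3.32), RPL10A (−2.08) and RPS18 (−7.21), all structural proteins of the ribosome, were among 15 members lower when adjusted over the list alone, against 0 over all genes. The median over all guides was only 57 and 98 reads in the JQ1 libraries, and this list lay far below the keratins and crystallins. The sizes of these member values are therefore uncertain. The transcription elongation list fell, with a median of −0.81 and 18 of 20 members lower (adjusted p = 0.0309; adjusted p = 0.889 with an estimated correlation). NELFCD (−1.97), a pausing factor, and CDC73 (−2.64), a PAF1 complex subunit, were its members lower when adjusted over the list alone. The spliceosome and RNA polymerase II list fell to −0.73 with 25 of 31 members lower (adjusted p = 0.0462; adjusted p = 0.889 with an estimated correlation), and the splicing proteins SF3A1 (−3.62) and SF3A3 (−4.03) were among its strongest members. The complex I list rose, with a median of 0.22 and 20 of 36 members above 0 (adjusted p = 0.0299; adjusted p = 0.889 with an estimated correlation), and its member NDUFA9 had a median of 3.16. The median of all guides' gene medians moved with the scaling, from 0.13 under TMM to 0.45 under RLE and −0.18 under total counts. With only the libraries of this comparison the elongation (0.197), spliceosome (0.384) and complex I (0.0855) calls ended as well. With total counts alone the elongation (adjusted p = 0.13) and spliceosome (adjusted p = 0.489) calls ended, and with RLE the complex I call ended (adjusted p = 0.102). The filter on mean count ended elongation (0.207) and spliceosome (0.169), the first run alone ended spliceosome (0.139) and complex I (0.0555), and the additional run alone (0.0766) and the replicate block (0.0889) ended spliceosome. By fry 0 of 45 lists passed (0.0742 for the ribosome, 0.112 for elongation, 0.412 for spliceosome and 0.679 for complex I). Without DMSO replicate 1 the elongation p was 0.257 and the spliceosome p 0.766. Without JQ1 replicate 1 these were 0.186 and 0.489. Without JQ1 replicate 2 the elongation p was 0.294 and the complex I p 0.826, and without DMSO replicate 2 the complex I p was 0.633.

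The comparison of CPI-0610 with DMSO in parental cells at day 21 asked the same of a second BET inhibitor. The titles of both DMSO libraries end in L008 and those of both CPI-0610 libraries in L007. Whatever this suffix marks cannot be told apart from the treatment. Guides against BAX, which opens the mitochondrial membrane in apoptosis, rose by a median of 2.19 log2 units (adjusted p = 0.0176). The BAX level was 5.62 ± 0.75 log2 CPM (SD, n = 2) under CPI-0610 against 3.0 ± 0.00 (SD, n = 2) under DMSO. Guides against ARNT, the shared partner of HIF1A and AHR in transcription, rose by 2.69 (adjusted p = 0.0234), from 2.95 ± 0.58 (SD, n = 2) to 5.49 ± 0.96 (SD, n = 2). The fatty acid desaturase gene SCD (1.88, adjusted p = 0.0234), the ERK phosphatase gene DUSP6 (1.81, adjusted p = 0.0396) and the AP-1 factor gene JUNB (1.76, adjusted p = 0.0422) also rose. Guides against HIF1A, the oxygen-sensing transcription factor, fell by 1.67 (adjusted p = 0.0176), from 5.03 ± 0.05 (SD, n = 2) to 3.35 ± 0.07 (SD, n = 2). The ubiquitin ligase adaptor ASB7 had a median of −2.44 (adjusted p = 0.0176) and a level of 0.74 ± 0.07 (SD, n = 2) against 3.21 ± 0.00 (SD, n = 2). CCM2 (−2.31, adjusted p = 0.0234), a scaffold of the MEKK3 pathway, BRMS1 (−2.02, adjusted p = 0.0483), a SIN3 corepressor subunit, and SLC12A7 (−1.22, adjusted p = 0.0492), a potassium chloride transporter, fell too. The BAX guides lay in exons 3 and 4 on chromosome 19 between 49459469 and 49464091. In all, 5 genes rose and 5 fell, against 941 and 999 at an unadjusted p under 0.05, while limma on gene means called 0 (1025 at an unadjusted p under 0.05). edgeR called 0 single guides (5034 at an unadjusted p under 0.05), and DESeq2 called 532 higher and 222 lower. In a fit without the parental day 14 libraries, chosen after the data were seen, edgeR called 3202 single guides.

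**Figure D2:**
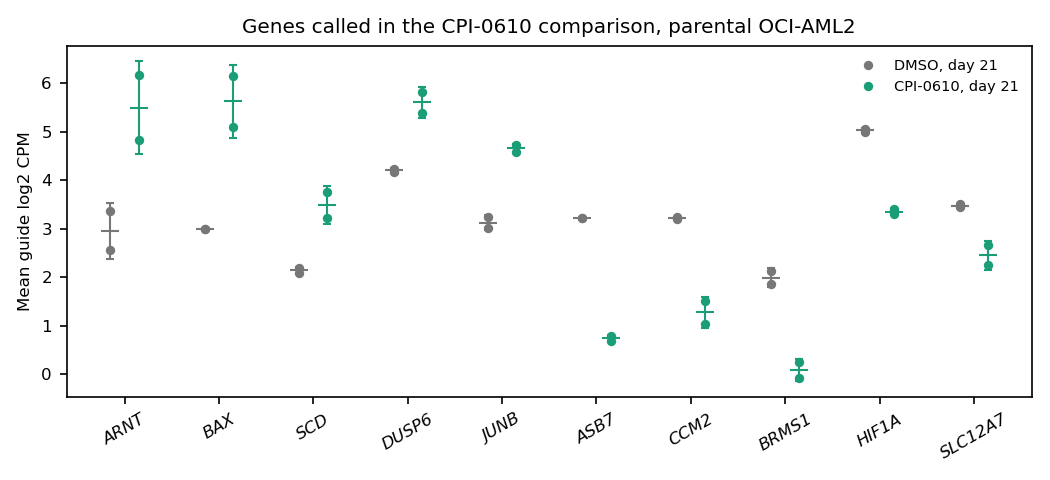
Mean guide log2 CPM of the 10 genes called in the CPI-0610 comparison, per library (points), with mean ± SD (n = 2) for DMSO (grey) and CPI-0610 (green) at day 21. In each of the 10 genes both CPI-0610 libraries lay on 1 side of both DMSO libraries.

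BAX passed the CPI-0610 test whichever of the 4 libraries was left out. Of 15 other settings it passed in 14, ASB7 and HIF1A in 13, CCM2 in 12, ARNT and BRMS1 in 9, DUSP6, JUNB and SCD in 8 and SLC12A7 in 4. Without CPI-0610 replicate 1 the adjusted p was 0.0835 for ASB7, 0.233 for HIF1A, 0.0908 for CCM2, 0.389 for BRMS1, 0.345 for SLC12A7, 0.689 for ARNT, 0.538 for DUSP6 and 0.216 for JUNB, and 4 genes passed in all. Without CPI-0610 replicate 2 it was 0.0633 for CCM2, 0.664 for SLC12A7, 0.719 for SCD, 0.304 for DUSP6 and 0.144 for JUNB, and 6 genes passed. Without DMSO replicate 1 it was 0.0843 for CCM2, 0.281 for BRMS1, 0.481 for SLC12A7, 0.0668 for ARNT, 0.0644 for SCD, 0.0615 for DUSP6 and 0.0668 for JUNB, and 4 genes passed. Without DMSO replicate 2 it was 0.191 for SCD, 0.468 for DUSP6 and 0.206 for JUNB, and 13 genes passed.

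Under CPI-0610 the list of SAGA and ATAC histone acetyltransferase subunits rose, with a median of 0.39 against −0.10 for all genes and 13 of 21 members higher (adjusted p = 0.000485; adjusted p = 0.374 with an estimated correlation), led by the deubiquitinase USP22 (1.15) and the acetyltransferase KAT2A (0.95). The mTORC1 activators rose with a median of 0.37 (adjusted p = 0.00429; adjusted p = 0.374 with an estimated correlation), with the amino acid sensing GTPase RRAGA at 1.29. The Wnt effectors rose with 14 of 16 members higher (adjusted p = 0.0134; adjusted p = 0.374 with an estimated correlation), with TCF7L2, a DNA-binding partner of beta-catenin, at 1.02. The list of the oxidative stress regulators KEAP1 and NRF2 with their targets fell, with negative values in 10 of 10 members and GCLC of glutathione synthesis at −1.37. Its adjusted p was 0.0168 by camera, 0.519 with an estimated correlation and 0.169 with the filter on mean count. No member passed the gene test over all genes. The HBO1, NuA4 and MOZ acetyltransferases (adjusted p = 0.0188; adjusted p = 0.836 with an estimated correlation) and the Mediator core (adjusted p = 0.0188; adjusted p = 0.836 with an estimated correlation) fell, with BRD1, a scaffold of such acetyltransferases, at −0.95 and MED28 of Mediator at −1.44. By fry 0 of 45 lists passed. Without CPI-0610 replicate 2 the calls of KEAP1 and NRF2 (0.137), HBO1 (0.31) and Mediator (0.31) ended. Without DMSO replicate 1 that of KEAP1 and NRF2 (0.0699) ended, and without DMSO replicate 2 those of Wnt (0.0844), Mediator (0.0844) and HBO1 (0.174) ended. The median of all gene medians was −0.06 under TMM, 0.00 under RLE and −0.18 under total counts.

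In JQ1-resistant cells the comparison of JQ1 with DMSO at day 14 asked which knockouts changed the growth of cells already resistant to the drug. No gene passed, but the genes nearest to the threshold on the higher side were FLCN, FNIP1 and RRAGC, which act together in amino acid signalling to mTORC1 and TFE3. FLCN guides had a median of 1.54 with 5 of 5 higher (adjusted p = 0.0703), and levels of 3.90 ± 0.63 log2 CPM (SD, n = 2) under JQ1 against 2.44 ± 0.08 (SD, n = 3) under DMSO. RRAGC had a median of 2.02 with 5 of 5 guides higher (adjusted p = 0.0703) and FNIP1 of 1.34 with only 3 of 5 higher (adjusted p = 0.111). On the lower side PDE4DIP, a centrosome and Golgi protein, had a median of −0.43 (adjusted p = 0.105), the sulfotransferase SULT6B1 −3.81 (adjusted p = 0.292) and the lipid scramblase TMEM41B −1.32 (adjusted p = 0.292). The Polycomb methyltransferase subunits EZH2 (1.94, adjusted p = 0.662) and EED (1.92, adjusted p = 0.76) were higher without passing. Robust rank aggregation on edgeR p-values called 0 genes (894 higher and 934 lower at an unadjusted p under 0.05), and limma called 0 higher and 1 lower. DESeq2 called 416 single guides higher and 641 lower. In a fit without the parental day 14 libraries, chosen after the data were seen, edgeR called 2101. In the main fit edgeR called 5 of 88401 single guides, all at an adjusted p of 0.0415. The called guides target TNFRSF14 (3.44), a lymphoid receptor, TMEM11 (3.73), a mitochondrial membrane protein, TNFSF13 (4.03), a B-cell cytokine, PIGP, of GPI anchor synthesis, and FUT1, a fucosyltransferase. The PIGP guide had 1, 0 and 0 reads under DMSO and 158 and 229 under JQ1, and the FUT1 guide had 175, 156 and 265 under DMSO and 1 and 0 under JQ1. These 5 guides were chosen after their values were seen, and the medians of all 5 guides of each of these genes were only 0.01, 0.78, 0.05, 0.28 and −0.12 in the same order. None of the 5 guide calls was made when any of the 5 libraries was left out. Without DMSO replicate 2 FLCN, RRAGC and PDE4DIP passed, without JQ1 replicate 2 FLCN and RRAGC passed, and without JQ1 replicate 1 only LEO1 passed.

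Of 45 gene lists with members, camera called 0 in the resistant JQ1 comparison (9 at an unadjusted p under 0.05, lowest adjusted p = 0.211), and fry called 0. Adjusted over the list alone, guides against EZH2, EED, the Polycomb genes RING1 and BCOR, USP22, the cell-cycle inhibitor CDKN2A, the growth restrainers TSC1 and FLCN and the GTPases RRAGA and RRAGC were higher. The elongation factor LEO1, the RB relative RBL1 and the autophagy scaffold RB1CC1 were lower by the same measure, and 0 of all these passed over all genes. RING1 had a median of only 0.05 with 3 of 5 guides higher, so its result rests on some of its guides. The median of all gene medians was −0.06 under TMM, −0.02 under RLE and −0.15 under total counts.

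**Figure D3:**
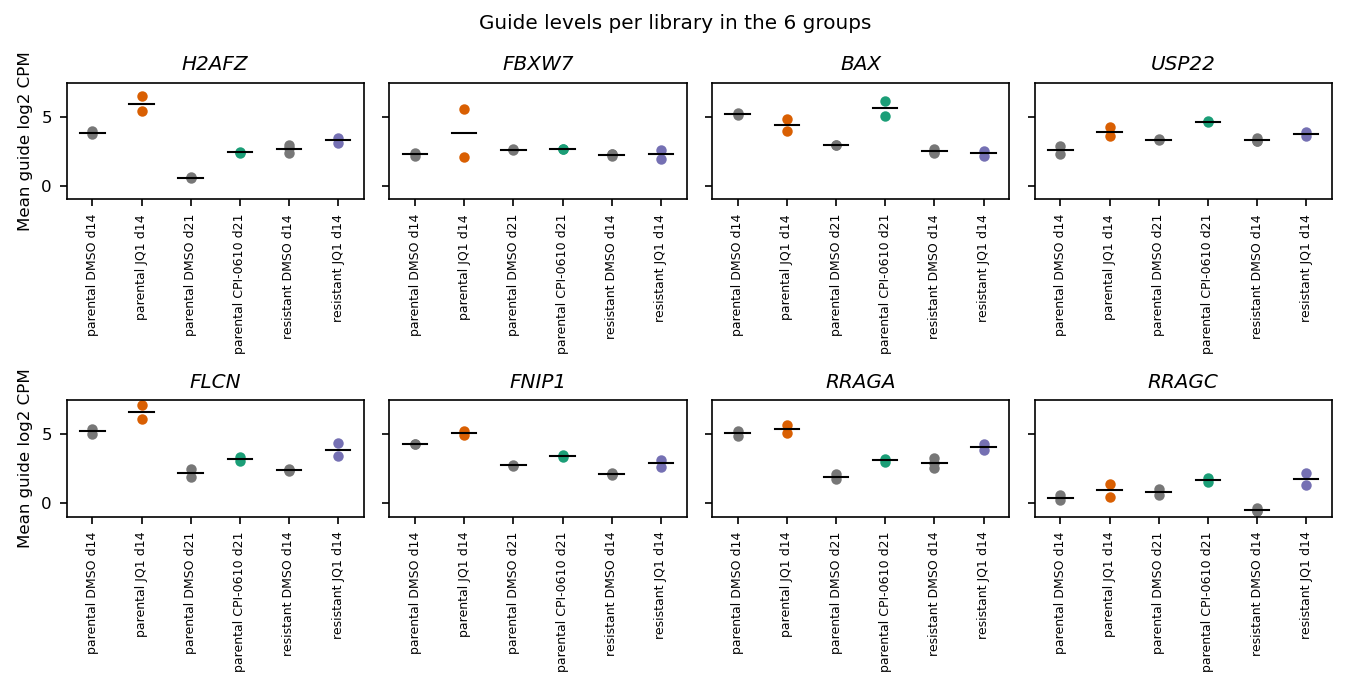
Mean guide log2 CPM of 8 genes, chosen after their values were seen, in each library (points) of the 6 groups with group means (bars). FBXW7 under parental JQ1 is carried by 1 of 2 libraries, and BAX is higher in parental DMSO at day 14 than at day 21.

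Between JQ1 at day 14 and CPI-0610 at day 21 in parental cells, guides against BAX differed by −3.83 log2 units (adjusted p = 0.0352), taken as the median of the differences of single guides, and their medians were −0.06 under JQ1 and 2.19 under CPI-0610. Guides against ATP6V0C, a subunit of the proton pump that acidifies lysosomes, differed by −4.32 by the same measure (adjusted p = 0.0352), and their medians were −3.63 and −0.11. The ATP6V0C guides had 0 to 2 reads each in the JQ1 libraries and 0 to 37 in DMSO of day 14. The size of that difference thus rests on few reads. H2AFZ, chosen after its values were seen here, had medians of 2.74 under JQ1 and 2.04 under CPI-0610 (adjusted p = 0.247 for the latter). The cytosolic ribosome list was lower under JQ1, with a median difference of −0.83 (adjusted p = 0.00263; adjusted p = 0.967 with an estimated correlation). Complex I (0.49, adjusted p = 0.0492; adjusted p = 0.967 with an estimated correlation) and the HBO1, NuA4 and MOZ list (0.61, adjusted p = 0.0492; adjusted p = 0.967 with an estimated correlation) were higher. The doses are unknown, and the days and library batches differ with the compound. The ribosome call ended under total counts (0.0717) and the calls of complex I and HBO1 under RLE (0.103 each). There the median of all gene medians, a measure unlike that of the list values, moved from 0.18 under TMM to −0.05 and 0.42. With no guide filter complex I and HBO1 also ended (0.0738 each), as did HBO1 with the additional run alone (0.0784). Complex I ended under the filter on mean count (0.12), the replicate block (0.0563) and the first run alone (0.0789) too. The calls of BAX and ATP6V0C ended under total counts, with the filter on mean count and in limma, which called 0 genes (1696 at an unadjusted p under 0.05). The adjusted p of BAX was 0.33 without CPI-0610 replicate 1, 0.352 without DMSO replicate 1 of day 14, 0.331 without JQ1 replicate 2, 0.0527 without JQ1 replicate 1, and 0.0586 and 0.0703 without DMSO replicate 1 and 2 of day 21. That of ATP6V0C was 0.659 without DMSO replicate 1 of day 14, 0.617 and 1 without JQ1 replicate 1 and 2, 0.0703 and 0.1 without CPI-0610 replicate 1 and 2, and 0.082 without DMSO replicate 2 of day 21. Without JQ1 replicate 2 the ribosome p was 0.303, the complex I p 0.706 and the HBO1 p 0.69, and without DMSO replicate 1 of day 14 the ribosome p was 0.0805. Without DMSO replicate 2 of day 14 the complex I p was 0.375 and the HBO1 p 0.211, without CPI-0610 replicate 2 they were 0.125 and 0.164, without CPI-0610 replicate 1 complex I was at 0.0733, and without DMSO replicate 2 of day 21 HBO1 was at 0.13.

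Between the resistant and the parental line, the effect of JQ1 on ribosomal protein genes was less negative in the resistant cells. Relative to the keratins and crystallins, these genes lay at −0.7 in resistant DMSO and −1.0 in resistant JQ1, against −3.6 and −4.4 in parental cells. Whether the smaller effect only follows from this weaker depletion was not tested. The cytosolic ribosome list differed by a median of 0.71 with 41 of 52 members higher (adjusted p = 0.0097; adjusted p = 0.928 with an estimated correlation), and 10 members passed when adjusted over the list alone against 0 over all genes. The PRC1 list of Polycomb ubiquitin ligase subunits differed by 0.64 with 19 of 20 members higher (adjusted p = 0.0387 by camera, and 0.928 with an estimated correlation). It was led by BCOR (2.05) and PCGF1 (1.81), partners in a non-canonical complex that represses transcription. For both genes the parental JQ1 libraries lay far apart, at 2.54 ± 1.88 log2 CPM (SD, n = 2) for BCOR and 1.2 ± 2.34 (SD, n = 2) for PCGF1. The parental DMSO levels were 3.71 ± 0.04 (SD, n = 2) and 3.34 ± 0.12 (SD, n = 2). Complex I differed by −0.27 (adjusted p = 0.0485; adjusted p = 0.928 with an estimated correlation). The median of all gene medians was −0.20 under TMM, −0.48 under RLE and 0.04 under total counts, and the median of PRC1 gene medians was 0.06, −0.22 and 0.27. These are medians of guide fold changes, a measure unlike that of the list values above. PRC1 thus changed sign with the shift of all genes, and relative to all genes it stayed higher by 0.25, 0.25 and 0.23. No single gene passed by robust rank aggregation on edgeR p-values (949 higher and 929 lower at an unadjusted p under 0.05, lowest adjusted p = 0.416) or by limma (1782 at an unadjusted p under 0.05). FBXW7, chosen after its values were seen, differed by −2.09 (adjusted p = 0.836). The ribosome call ended under total counts (0.249) and PRC1 with the replicate block (0.0572). Complex I ended under RLE (0.13), the replicate block (0.083), no guide filter (0.0647) and the filter on mean count (0.0533). Without parental DMSO replicate 1 the ribosome p was 0.175, and without parental JQ1 replicate 2 the p was 0.297 for the ribosome, 0.218 for PRC1 and 0.798 for complex I. Without parental DMSO replicate 2 it was 0.0891 for PRC1 and 0.554 for complex I, and 6 genes, among them RPL13 and RPL19, passed as higher. Without parental JQ1 replicate 1 PRC1 was at 0.0743, and FBXW7 and PTPN1 passed as lower. Without resistant JQ1 replicate 1 the 3 lists were at 0.0613, without resistant DMSO replicate 3 PRC1 and complex I were at 0.0675, and complex I was at 0.0834 without resistant JQ1 replicate 2 and 0.0501 without resistant DMSO replicate 1.

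Between the DMSO libraries of the resistant and the parental line at day 14, guides against the topoisomerase gene TOP3A (4.39, adjusted p = 0.0439) and CCNF, which encodes cyclin F (2.84, adjusted p = 0.0439), were higher in the resistant line. Guides against E2F8, a repressor of E2F targets, were lower, with a median of −7.23 (adjusted p = 0.0105), those against TRERF1, a transcription regulator, with −6.10 (adjusted p = 0.00586), and those against ASB3, a ubiquitin ligase adaptor, with −5.09 (adjusted p = 0.00586). The E2F8 level was 2.49 ± 0.16 log2 CPM (SD, n = 3) in resistant against 8.17 ± 0.15 (SD, n = 2) in parental cells of day 14, and it was 2.76 ± 0.18 (SD, n = 2) in parental cells of day 21. The myeloid differentiation factor CEBPD (−4.36, adjusted p = 0.00586) and the acetyltransferase scaffold BRD1 (−4.35, adjusted p = 0.0205) were lower as well. The other lower genes, chosen after their values were seen, were RC3H1 (−4.20, adjusted p = 0.0377), which degrades mRNA, CEBPE (−4.13, adjusted p = 0.0391) of granulocyte differentiation, RREB1 (−3.83, adjusted p = 0.00879), a RAS-responsive factor, and the CDK4 and CDK6 inhibitor CDKN2C (−2.89, adjusted p = 0.0391). In parental DMSO at day 21 the levels of TRERF1 (2.97), ASB3 (3.52), CEBPD (2.74), BRD1 (2.94), RC3H1 (3.59), CEBPE (3.23), RREB1 (3.88), CDKN2C (4.10) and CCNF (3.51) lay far nearer to the resistant line than to parental day 14, so for these genes the parental libraries of day 14 stood apart from both. TOP3A had 0.67 ± 0.63 (SD, n = 2) at day 21, between −1.14 ± 1.07 (SD, n = 2) in parental cells of day 14 and 2.05 ± 0.86 (SD, n = 3) in resistant cells. Robust rank aggregation called 3 genes higher and 9 lower, against 1311 and 1043 at an unadjusted p under 0.05, and limma called 5601 higher and 2391 lower. Of 14 settings apart from omitted libraries, ASB3, CEBPD, E2F8 and TRERF1 passed in 14, RREB1 in 13 and BRD1 and CEBPE in 12. CCNF passed in 10 of these settings, and TOP3A, CDKN2C and RC3H1 in 9. ASB3, BRD1, CEBPD, E2F8, RREB1 and TRERF1 passed whichever of the 5 libraries was left out. Without parental replicate 2, TOP3A (0.281), CCNF (0.119) and CDKN2C (0.051) did not pass. Without resistant replicate 1, TOP3A and CCNF were at 0.0738, CEBPE and RC3H1 at 0.0703 and CDKN2C at 0.0603. Without resistant replicate 3, TOP3A and CCNF were at 0.0644 and CEBPE at 0.0615, without resistant replicate 2 RC3H1 was at 0.0686, and without parental replicate 1 CCNF was at 0.0615. The count was 33 without parental replicate 1 and 6 without resistant replicate 1. BRD2, BRD3, SPOP, TRIM33, EZH2, EED and SUZ12, examined in every comparison, did not pass in any of the 6.

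Of the gene lists, 12 were higher in resistant than in parental DMSO cells and none was lower. The mitochondrial ribosome was higher by a median of 2.95 in 72 of 72 members (adjusted p = 3.37e-17), the spliceosome and RNA polymerase II by 3.43 in 31 of 31 (adjusted p = 1.7e-10), the cytosolic ribosome by 3.15 (adjusted p = 1.47e-09) and complex I by 3.05 (adjusted p = 1.47e-09), against 0.38 for all genes (each with an adjusted p of 0.327 with an estimated correlation). The proteasome (2.83), the Mediator core (2.56), Integrator (3.06 in 14 of 14 members), the MLL and menin complex (2.67 in 12 of 12), elongation factors (2.18 in 20 of 20) and SAGA and ATAC (1.86) were higher with adjusted p-values of 2.07e-06 to 0.00243 (0.327 to 0.416 with an estimated correlation). The HBO1, NuA4 and MOZ list (1.91, adjusted p = 0.0438) and Cullin-RING regulators (1.61, adjusted p = 0.0493) were higher, though both ended under RLE (0.0633 each) and total counts (0.198 and 0.119), and both had an adjusted p of 0.623 with an estimated correlation. Both also ended under the filter on mean count (0.0814 and 0.297), with only the libraries of this comparison (0.0673 and 0.0701), with the replicate block (0.101 and 0.12) and with the additional run alone (0.0562 each), and Cullin-RING with the first run alone (0.0871). Without parental replicate 2 HBO1 was at 0.113 and Cullin-RING at 0.172, and without resistant replicate 3 they were at 0.05 and 0.0637. The median of all gene medians was 0.18 under TMM, 0.32 under RLE and 1.03 under total counts, and fry, which does not compare a list with other genes, called 37 of 45 lists here and 0 in each of the other 5 comparisons.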

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

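All tests of explanations in this part were chosen after the results were seen; the contrasts between effects were planned.

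The tests of a difference between effects picked out 8 results. Between JQ1 and CPI-0610 in parental cells, ATP6V0C differed by −4.32, on 0 to 37 reads per guide at day 14, and BAX by −3.83 log2 units. Between the same effects, the cytosolic ribosome differed by −0.83, complex I by 0.49 and the HBO1, NuA4 and MOZ list by 0.61. Between the resistant and parental JQ1 effects, the cytosolic ribosome differed by 0.71, PRC1 by 0.64 and complex I by −0.27. None of these 6 list differences passed with an estimated correlation (adjusted p = 0.928 and 0.967). All 8 share the parental JQ1 libraries, whose gene effects did not repeat between replicates.

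BAX guides rose under CPI-0610 and not under JQ1, and the 2 DMSO baselines differed. The mean level of the BAX guides stood 2.22 ± 0.08 (SE) log2 units higher in parental DMSO at day 14 than at day 21. Not all guides shared this. The guide starting at 49459469 had 199 and 284 raw reads at day 14 against 756 and 467 at day 21. The guide starting at 49464068 had 324 and 267 against 311 and 437. Under JQ1 they changed by −2.26 and 0.57 log2 units, and under CPI-0610 by 2.19 and 2.08. For the other guides only, a higher starting level at day 14 is a candidate explanation for the absence of a rise under JQ1. A lack of room to rise cannot be told apart from it: 1.1% of the 174 genes at the BAX level were over 1 log2 unit higher under JQ1 against 2.58% of all genes, too few to decide. Library batch, day and compound differ together between the comparisons, and a difference between the compounds was not tested apart from these.

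FBXW7 guides were higher in parental JQ1 replicate 2 and not in replicate 1. An expansion of 1 or 2 guides is excluded, since 11 of 11 guides lay over 1 log2 unit above the DMSO mean in replicate 2. The spread of effects over all genes in replicate 2 was 0.87 times that of replicate 1, so it was not wider as a whole. This ratio cannot exclude wider rises in replicate 2, since the libraries differed in their low counts. Guides with 0 reads made up 13.35% of replicate 1 and 5.1% of replicate 2. The top 1% of guides took 19.87% and 23.53% of the reads. A difference between the cultures or an effect of the drug that arose in 1 of them may explain the pattern, and neither was tested.

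Guides against essential genes were less depleted in resistant than in parental DMSO libraries at day 14. Library scaling is excluded, since the difference measured within each library was 2.96 ± 0.42 (SE) log2 units, and so is depth, since it was 3.23 ± 0.42 (SE) after thinning the 5 libraries to the same median reads per keratin and crystallin guide, though the unevenness between guides was not matched and stays open. The share of the parental depletion kept by the 5 essential lists spanned 8.7 percentage points (10.2% to 19.0%). With every list near 0 in the resistant line a wide span could hardly arise, so the span cannot decide whether all lists were alike. In the resistant DMSO libraries the cytosolic ribosome (−0.73 to −0.64) and complex I (−0.42 to −0.29) did not overlap. Less dropout of all essential genes alike, as from less editing or fewer cell divisions, stays open. The parental DMSO libraries of day 21 lay between them, at −2.18 and −2.10, so part of the gap sets the parental day 14 libraries apart, and the biological difference between the lines stays open.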

How the results depend on the processing

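The fit without the parental day 14 libraries was chosen after the data were seen, and the other alternatives were planned. Causes are given only where the alternative's own construction shows them; otherwise the cause was not tested. No call reversed its direction. Of the tests of called lists under alternatives, 331 still passed and 136 no longer passed. The tests of named genes also covered genes that did not pass in the main fit. Of these tests 3526 kept their side of the threshold, which is therefore not a count of kept calls. A further 165 no longer passed, 132 newly passed and 138 changed sign without passing in either fit.

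The replicate numbers were also used as a block, although labels share numbers only: correlations across guides of the differences between numbers in treated and control libraries were 0.135 for parental JQ1, −0.016 for CPI-0610 and −0.004 for resistant JQ1. With that block the parental JQ1 genes went from 2 to 0, the resistant guides from 5 to 0, the genes of the JQ1 and CPI-0610 difference from 2 to 1 and those of the line comparison from 12 to 7; 7 CPI-0610 genes passed against 10.

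DESeq2 called 6396 guides for parental JQ1, 754 for CPI-0610 and 1057 for resistant JQ1, where edgeR called 0, 0 and 5, and its guide p-values gave 2 resistant genes (FLCN and RRAGC). With only the libraries of a comparison, 46 guides were called for CPI-0610 and 5447 for resistant JQ1, 1 resistant gene passed (BCOR), and 0 genes passed for the JQ1 and CPI-0610 difference. Without the parental day 14 libraries, the most uneven, 3202 CPI-0610 and 2101 resistant guides were called. In the main fit all groups share 1 estimate of spread per guide, so these libraries enter the tests of the other comparisons. Between replicates the chi-squared value per degree of freedom was 332.37 for parental JQ1, 58.27 for CPI-0610 and 42.51 for resistant JQ1. The low guide counts of the main fit for the latter 2 thus depend on the parental day 14 libraries. The causes of the other counts were not tested.

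With alpha 0.05 the gene counts were 0 for parental JQ1, 4 for CPI-0610, 0 for the JQ1 and CPI-0610 difference and 5 for the line comparison. Without each gene's strongest guide they were 5 for parental JQ1 and 22 for the line comparison. Counts summed per gene called 70 parental JQ1, 6 CPI-0610, 30 resistant, 0 JQ1 and CPI-0610 difference and 7824 line comparison genes, and limma called 8, 0, 1, 0 and 7992. The last 2 tests read a shift of a whole gene's guides against the spread between libraries, not the ranks against other genes. For the JQ1 and CPI-0610 difference, total counts, the mean count filter and the additional run alone gave 0 genes and the first run alone 1. The first run alone gave 2 resistant genes, and the additional run alone 2 resistant guides. The cause was not tested.

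Leaving out each library in turn gave 0 to 24197 guides and 0 to 20 genes for parental JQ1, 0 to 0 guides and 4 to 13 genes for CPI-0610, and 0 to 0 guides and 0 to 3 genes for resistant JQ1. It gave 0 to 6 genes for the resistant and parental difference, 0 to 3 for the JQ1 and CPI-0610 difference, 6 to 33 for the line comparison and 22 to 33 lists against 30. With an estimated correlation 0 of the 30 lists passed. Under the 15 planned and added settings apart from omitted libraries, BAX passed for CPI-0610 in 14, ASB7 and HIF1A in 13, CCM2 in 12, ARNT and BRMS1 in 9, DUSP6, JUNB and SCD in 8 and SLC12A7 in 4, which ended under RLE, total counts and DESeq2 among others. Most simulated changes of 1 log2 unit were missed, and other depths were not simulated. The chi-squared value per degree of freedom was 2.04 to 2.98 between runs of a library and 18.01 to 332.37 between replicates, so spread between libraries exceeded counting error.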

Other observations

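The genes in this part were chosen after their values were seen, as were all its tests.

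Under CPI-0610 the guides of AHR, which pairs with ARNT to sense small molecules, had a median of 2.52 (adjusted p = 0.287), beside 2.69 for ARNT and −1.67 for HIF1A. The AHR level was 3.19 ± 1.23 log2 CPM (SD, n = 2) against 1.70 ± 0.28 (SD, n = 2) under DMSO, so its 2 CPI-0610 libraries lay far apart. The partners of CCM2 in a vascular signalling scaffold, KRIT1 (−2.10, adjusted p = 0.254) and PDCD10 (−1.95, adjusted p = 0.663), were lower without passing. TSC1 (2.09, adjusted p = 0.326) and TSC2 (1.96, adjusted p = 0.316), which together restrain mTORC1, were higher without passing.

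FLCN, FNIP1, RRAGA and RRAGC act in one nutrient signalling pathway, and their guides had medians of 1.54, 1.34, 0.70 and 2.02 under JQ1 in the resistant line, where none passed (adjusted p = 0.0703, 0.111, 0.461 and 0.0703). The hypothesis was that their loss may also favour parental cells under a BET inhibitor. Their median was 1.15 under parental JQ1 (one-sided permutation p = 0.0028 among 100000 random sets of 4 genes) and 1.19 under CPI-0610 (permutation p = 1e-05, the smallest these draws can give). RRAGC had 3 of 5 guides higher under CPI-0610 and a guide at −3.30, and its gene-test p was 0.0233 for higher and 0.00529 for lower guides. The permutation p-values take genes as independent. FLCN under parental JQ1 and CPI-0610, and FNIP1 and RRAGA under CPI-0610, were already known to be high when the set was drawn up. The permutation p-values thus rank the set without testing it on new data.

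FLCN and the deubiquitinase gene USP22 had a gene-test p under 0.01 for higher guides in all 3 drug comparisons, with medians of 1.33, 0.98 and 1.54 for FLCN and 1.45, 1.15 and 0.65 for USP22. Sets of these sizes would share 0.033 genes if independent. For lower guides 0 genes were shared, where 0.04 would be. Neither gene passed in any of the 3 comparisons after adjustment over all genes. Under parental JQ1, CPI-0610 and resistant JQ1, 5, 3 and 5 of the 5 FLCN guides were higher. For USP22 these were 5, 4 and 4 of 5.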
